A study of Mus musculus with 12 samples.

How the data were processed

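Whole brains of 6-week-old mice were profiled by sequencing of polyadenylated RNA, with 3 mice for each of 4 genotypes and 1 library per mouse. Per the labels, the brains were divided into pieces in RNAlater, RNA was extracted with TRIzol, and libraries were made with the TruSeq RNA v2 kit and read as 100 bp paired ends on an Illumina HiSeq instrument. That kit does not mark the strand, so reads from a gene and from an antisense partner cannot be told apart. The series design names 3 mice per genotype, so p-values measure the spread between separate animals. The 3 sample titles of h1 share 1 stem, as do the 3 of h2. Those of WT share none, and only that of replicate 3 has the form used for h1 and h2. The labels do not name litters or cages.

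The authors deposited 1 table of gene-level RSEM output per library. Per the submitters' processing notes, the tools were Bowtie2 2.2.0 and RSEM 1.2.12. The genome build and gene annotation behind the tables are not given in the sources used here. The deposited expected counts are RSEM's estimated numbers of read pairs per gene. A pair that matches several genes is shared among them, so a value need not be whole, and 77.7% of the values above 0 were exactly whole as printed with 2 decimals. The TPM values deposited by the authors are normalised to each library's own total and to the transcript length. The deposited FPKM values are per kilobase of transcript and scaled to the library's fragments, and were not used in a test. The authors' tables also give a length and an effective length per gene, which RSEM averages over the estimated mix of transcripts. Near-identical genes can exchange estimated counts in this procedure, so values of Hspa1a and Hspa1b, of Aldh1a1 against Aldh1a7, and of the H2-Q genes are uncertain as values of 1 copy.

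Genes carry Ensembl identifiers, of which 37607 of 38924 were found in the GENCODE M21 annotation of the GRCm38 build. Symbols, positions and GC content came from that annotation by identifier, for 98.7% of the genes tested. Libraries held between 14513800 and 24694200 expected counts. The common biological coefficient of variation was 0.0531, which means that mice of 1 genotype differed by about that fraction for a typical gene after counting error. In any pair of libraries of 1 genotype, gene counts differed by more than sampling noise, with a chi-square per degree of freedom of 2.38 to 4.47, so no library was a second copy of another of its genotype.

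Expected counts were rounded to whole numbers and tested with the quasi-likelihood method of edgeR 4.0.16 in R 4.3.3, with robust dispersion estimates. The low-count filter of edgeR left 16493 genes and removed 22431. Library totals were scaled by TMM, whose factors lay between 0.991 and 1.012. A single model with 1 mean per genotype was fitted to all 12 libraries, so that the 4 genotypes shared 1 estimate of spread. The 7 comparisons were each mutant against wild type, each pair of mutants, and the mean of the 3 mutants against wild type. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, and every adjusted p of a gene is from edgeR unless another tool is named. CPM values are expected counts scaled to the library total. For Rorb, Il1r1, Tyr and the estimated length of Rorb, 2-sided exact permutation tests were added, whose smallest possible p with 3 against 3 libraries is 0.1.

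A total of 39 gene lists with 702 entries, covering brain regions, cell types, signalling programmes and the neighbours of 2 loci, was written before the data were examined, as were the comparisons, the tests, the alternatives below and the rule for naming genes. Of their 664 distinct genes, 603 were measured. Lists were tested with camera of limma 3.58.1, which asks whether a list's genes moved more than other genes, with a preset correlation between genes of 0.01 and again with the correlation estimated from the data. The fry test of limma asks whether the genes of a list move, on balance, in 1 direction, and its mixed form whether they change in either direction, and neither compares the list with other genes. Adjusted p of lists are over the 39 lists of a comparison. Fisher's exact test, 2-sided, compared the share of called genes within 20 Mb of Rorb, Il1r1 and Tyr, and on each chromosome, with the share elsewhere.

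The rule named Rorb, Il1r1 and Tyr in every mutant, and then the 10 largest rises and 10 largest falls among called genes with a mean of at least 1 CPM over both groups and no overlap between their libraries. For a pair of mutants the number was 5 each way. Predicted genes named Gm or Rik, pseudogenes and genes with no symbol were counted and not named. The rule also took up to 15 genes called in the same direction in all 3 mutants, and up to 4 members per list with the smallest adjusted p, or up to 2 members of highest CPM where no member was called. Values of 3 genes that this rule took are not reported here.

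The same steps were tested on simulated counts drawn from the means and totals of these libraries. For h1 against wild type, 16361 genes entered the step, and 56 percent of changes of 1.25-fold and 90 percent of changes of 1.5-fold were recovered. For h2 against wild type the shares were 52 and 80 percent over 16351 genes, and for h4 against wild type 66 and 84 percent over 16369 genes. In these simulations 4.71, 3.30 and 5.05 percent of the calls for h1, h2 and h4 were unchanged genes. These shares were 6.70 percent for h2 against h1, 3.89 for h4 against h1, 4.74 for h4 against h2 and 7.55 for the mean of mutants, so 3 of the 7 lay above 5 percent. A simulated shift of 1 whole list was found by camera in each of the 7 comparisons, with at most 1 other list passing. Each comparison was simulated 1 time, with genes drawn independently. The simulation therefore cannot show how often camera passes lists whose genes vary together.

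Alternatives were the size factors of DESeq2, the full DESeq2 1.42.0 test, no low-count filter, a stricter filter of 1 CPM in 3 libraries, a model of only the groups compared, limma on log2(TPM + 0.5), the log2 CPM of Xist as a covariate, offsets for gene length and for GC content (loess, span 0.3), windows of 10 and 40 Mb, the replicate number as a block, and leaving out each library in turn. A fit to only the 7 libraries with Xist above 100 CPM was chosen after seeing the data. Sex is not recorded in the labels. Xist, transcribed from the inactive X chromosome of females, and Ddx3y of the Y chromosome were very uneven between libraries.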

Results

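The data collected were gene-level expression values of 12 whole brains, 3 each from wild type (WT) mice and from mice homozygous for the h1, h2 or h4 allele of Rorb. These alleles belong to the high stepper series, named for the mutants' gait. The comparisons address how each allele changes the brain transcriptome and what the alleles share. Per the labels, WT and h1 mice were on the C57BL/6J background, h2 mice on B6(Cg)-Tyrc-2J/J and h4 mice on B6.129S7-Il1r1tm1Imx/J, so background and allele cannot be separated for h2 and h4. The libraries held 20168800 to 21472400 expected counts in WT, 20310900 to 24000800 in h1, 14513800 to 24694200 in h2 and 17667300 to 18388700 in h4.

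Rorb encodes an orphan nuclear receptor of the ROR family that marks layer 4 neurons of the neocortex. Its gene (ENSMUSG00000036192) lies on the minus strand of chromosome 19 at 18930605 to 19111196 in GRCm38. Its level was 17.3 ± 1.13 CPM in WT (SD, n = 3), 26.5 ± 5.99 in h1, 28.2 ± 4.98 in h2 and 8.76 ± 0.274 in h4. By library, these were 18.5, 16.3 and 17.04 CPM in WT, 23.3, 33.4 and 22.8 in h1, 31.1, 31.1 and 22.5 in h2, and 9.07, 8.64 and 8.56 in h4. All 3 h4 libraries lay below, and all h1 and h2 libraries above, every WT library. Rorb therefore fell in h4, with a log2 fold change of -0.98 (SE 0.20, edgeR adjusted p = 0.0309). In h1 the log2 fold change was 0.62 (SE 0.17, adjusted p = 0.242) and in h2 it was 0.70 (SE 0.17, adjusted p = 0.147), neither of which passed with edgeR on all libraries, while DESeq2 gave adjusted p of 0.00297 and 0.000292. With edgeR the rise in h2 passed without h1 replicate 2 (adjusted p = 0.0027) or h2 replicate 3 (0.0291), and the rise in h1 in no leave-out. The exact permutation p was 0.1 for each mutant against WT, the smallest that 3 against 3 libraries allow.

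The fall of Rorb in h4 kept its direction in the alternatives, while its adjusted p moved across the threshold. Its adjusted p was 0.0689 with Xist as a covariate, at a log2 fold change of -0.98 and an SE of 0.23. Without any single WT or h4 library the Rorb call was lost, with log2 fold changes from -1.02 to -0.93 and an adjusted p of at most 0.12. It was kept without any single h1 or h2 library, with an adjusted p of 9.34e-05 without h1 replicate 2. Between mutants, Rorb was lower in h4 than in h1 by a log2 fold change of -1.60 (SE 0.19, adjusted p = 0.00331) and than in h2 by -1.68 (SE 0.19, adjusted p = 0.00241). The deposited TPM of Rorb was 3.71 ± 0.314 in WT, 5.50 ± 1.24 in h1, 5.91 ± 0.987 in h2 and 1.91 ± 0.0603 in h4 (SD, n = 3). Its estimated transcript length was 9045 ± 104 bases in WT, 9154 ± 59.4 in h1, 9146 ± 203 in h2 and 8745 ± 188 in h4, with exact permutation p of 0.2, 0.6 and 0.2 against WT. The sources used here do not give the sequence change of each allele, and gene-level values do not show which exons were read.

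**Figure D1:**
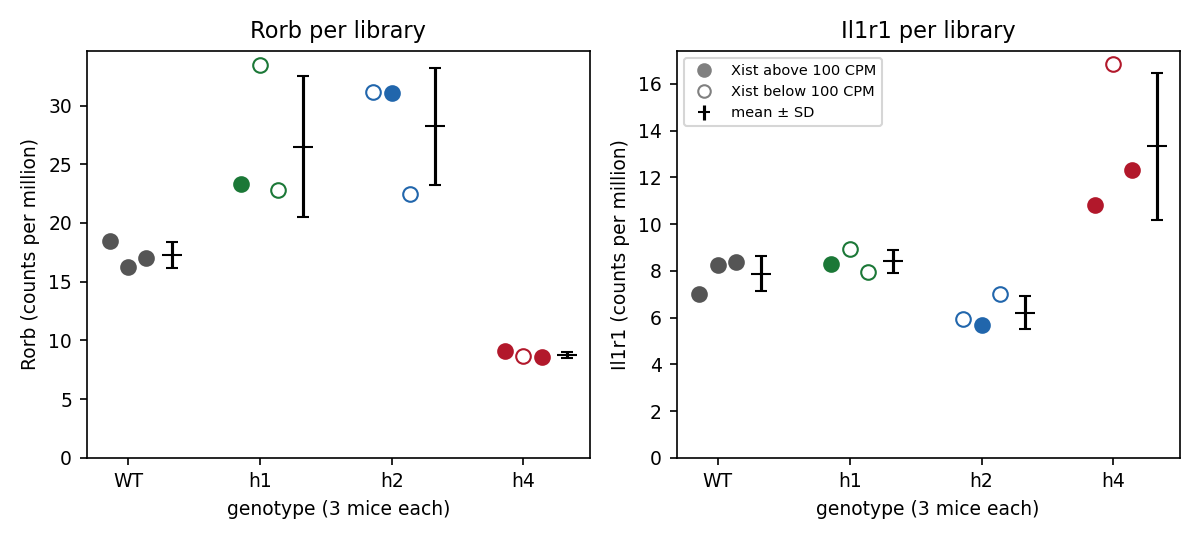
CPM of Rorb and Il1r1 in each of the 12 libraries by genotype, with filled points for libraries with Xist above 100 CPM, open points for those below, and bars at the mean ± SD of 3 libraries. Rorb lies between 16.3 and 18.5 CPM in WT and between 8.56 and 9.07 in h4, and Il1r1 reaches 16.8 CPM in h4.

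Il1r1, the signalling receptor for interleukin 1, carries a targeted allele in the h4 background strain. The gene (ENSMUSG00000026072) lies on the plus strand of chromosome 1 at 40225080 to 40317257. It measured 7.88 ± 0.741 CPM in WT, 8.40 ± 0.511 in h1, 6.21 ± 0.698 in h2 and 13.3 ± 3.14 in h4 (SD, n = 3). Il1r1 rose in h4 by a log2 fold change of 0.76 (SE 0.13, adjusted p = 0.00161), and it was also higher than in h1 (0.67, adjusted p = 0.00473) and in h2 (1.10, adjusted p = 7.64e-05). Against WT it was not called in h1 (0.09, adjusted p = 0.886) or h2 (-0.34, adjusted p = 0.351). Gene-level counts cannot check whether an exon is missing, so the level of Il1r1 does not check the strain. Tyr, the tyrosinase gene whose albino allele marks the h2 background, lies on the minus strand of chromosome 7 at 87424771 to 87493512 (ENSMUSG00000004651). It was near the detection limit, at 0.935 ± 0.119 CPM in WT, 1.04 ± 0.214 in h1, 1.37 ± 0.118 in h2 and 1.15 ± 0.395 in h4, and was not called in any comparison (h2 against WT 0.56, adjusted p = 0.433).

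Xist was at 786 to 911 CPM in 7 libraries and at 0.562 to 1.36 CPM in the other 5. Those 5 libraries had Ddx3y at 95.5 to 104 CPM, the 7 at 0.0407 to 0.149. The 5 mice thus read as male, the 7 as female. Xist was high in all 3 WT libraries, in 1 of 3 in h1, in 1 of 3 in h2 and in 2 of 3 in h4. The sex-linked list had no called member in any comparison, because these genes varied within groups. Every comparison of a mutant with WT therefore also differs in this Xist and sex composition, WT being all female.

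In h1 brains, 9 of 16 oligodendrocyte genes were higher than in WT, and 2 of 17 genes of endothelial and mural cells were lower. Mbp, which encodes myelin basic protein, rose by a log2 fold change of 0.34 (SE 0.04, n = 3 per group, adjusted p = 0.000681), from 4131 to 5213 CPM. Mobp rose by 0.35, Cldn11 by 0.31, Mal by 0.32 and Hapln2, a link protein of the nodes of Ranvier, by 0.49. Cldn5, the tight-junction claudin of endothelial cells, fell by 0.57 on the log2 scale (SE 0.10, adjusted p = 0.0115), from 30.3 to 20.4 CPM. Cd93 (-0.63) and Cdh5 (-0.34), which are also endothelial genes, fell too, and of these 3 only Cd93 stayed called with Xist as a covariate.

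In all, 103 genes were called in h1, 69 higher and 34 lower, with a median fold of 1.21. Of these, 4 changed more than 2-fold, and 3 without a usable symbol are not named. The libraries of all 103 did not overlap, against 14.5% of all genes tested and 10% by chance for 3 against 3. Calling selects for such genes, so the overlap of called genes is no separate evidence, here or in the comparisons below. The largest rises by the naming rule were Rtkn2 (0.60), Hoxb8 (0.54), Id1 (0.51), Hapln2, Tmem125 (0.46), Slc6a20a (0.43), Hist1h1c (0.40), Ptgds (0.38), Pnpla2 (0.38) and Pdlim2 (0.37). Ptgds, the brain prostaglandin D synthase, went from 581.7 to 759 CPM with an adjusted p of 0.00053. The largest falls were Slc22a2 (-1.31), Cd93, Itih2 (-0.61), Cldn5, Aldh1a2 (-0.49), Mmp14 (-0.49), Slc6a13 (-0.47), Robo3 (-0.44), Rbp4 (-0.43) and Klf10 (-0.37). Slc22a2, an organic cation transporter, went from 2.10 to 0.851 CPM (SE 0.26, adjusted p = 0.0115), and Itih2 from 13.5 to 8.82 CPM (SE 0.11, adjusted p = 0.00435).

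Of 16 measured oligodendrocyte genes in h1, 9 rose, none fell and 7 did not pass, and 12 rose when adjusted over the list alone. The camera adjusted p was 6.65e-27, and the adjusted p was 0.167 with an estimated correlation. Of 13 genes of oligodendrocyte precursors, 2 rose, Olig1 (0.27) and Olig2 (0.29), none fell and 11 did not pass (2 rose when adjusted over the list alone, camera adjusted p = 0.18). Of 17 endothelial and mural genes none rose, Cldn5 and Cdh5 fell and 15 did not pass (3 fell when adjusted over the list alone, camera adjusted p = 0.000702, adjusted p = 0.477 with an estimated correlation). Of 21 retinoid and nuclear receptor genes, Aldh1a1 (0.30) rose, the retinoic acid synthase Aldh1a2 and the retinol carrier Rbp4 fell and 18 did not pass. Adjusted over the list alone, 1 rose and 3 fell (camera adjusted p = 0.0241, adjusted p = 0.365 with an estimated correlation). Of 16 meningeal fibroblast genes, Aebp1 (0.32) rose, Slc6a13 and Aldh1a2 fell and 13 did not pass, with the same numbers when adjusted over the list alone (camera adjusted p = 0.464).

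Further lists passed camera in h1 with few or no called members. The 12 glucocorticoid-responsive genes had a median log2 fold change of 0.47 with none called and 5 higher when adjusted over the list alone (camera adjusted p = 1.15e-13, adjusted p = 0.167 with an estimated correlation). Sgk1 stood at 176 CPM against 99.2 in WT (adjusted p = 0.45), and Mt1 at 158 against 112 (adjusted p = 0.0624). The 23 immediate early genes pointed down, with Ier5 (-0.32) called and no rise (1 fell when adjusted over the list alone, camera adjusted p = 1.58e-06, adjusted p = 0.477 with an estimated correlation). The 20 interferon and MHC genes pointed down, with Lgals3bp (-0.32) called and 3 lower when adjusted over the list alone (camera adjusted p = 6.69e-05, adjusted p = 0.365 with an estimated correlation). Astrocyte genes (camera adjusted p = 0.000204, up, 4 higher when adjusted over the list alone) and protein folding stress genes (camera adjusted p = 0.000204, down, 2 lower when adjusted over the list alone) had no call, with adjusted p of 0.167 and 0.477 with an estimated correlation. Circadian, choroid plexus, mitochondrially encoded and nuclear oxidative phosphorylation genes, all up, and cerebellar genes, down, passed camera with no call (camera adjusted p = 0.0404, 0.0383, 0.00124, 0.028 and 0.00147). Their adjusted p were 0.506, 0.535, 0.535, 0.686 and 0.535 with an estimated correlation, and adjusted over the list alone 6 circadian genes were higher and 1 lower, and 1 cerebellar gene was lower. The Xist covariate ended the camera call of the circadian (adjusted p = 0.185), retinoid (0.069), mitochondrially encoded (0.323), oxidative phosphorylation (0.809) and cerebellar lists (0.498). In the channel list Cacna1g (-0.25) fell, with 2 lower when adjusted over the list alone, and its median of 0.01 and the direction of camera, down, differed in sign (adjusted p = 0.596). None of the 13 passing lists held with an estimated correlation, where the smallest adjusted p was 0.167.

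In h1, 4 of 102 genes tested within 10 Mb of Rorb were called (3.92%) against 0.606% elsewhere, an odds ratio of 6.69 (95% interval 1.75 to 18.2, Fisher's exact adjusted p = 0.0116). These were Aldh1a1 and, chosen after their values were seen, Fth1 (0.22), Myrf (0.22) and Psat1 (0.21), all higher. Within the 20 Mb window fixed beforehand, 6 of 354 were called (odds ratio 2.84, adjusted p = 0.0717). Of the 20 measured Rorb neighbours in the list for chromosome 19, Aldh1a1 alone rose and none fell, with 2 higher when adjusted over the list alone (camera adjusted p = 0.0827). Fitted with Xist as a covariate, which is high in 3 WT but only 1 h1 library, 27 genes were called in h1, 25 higher and 2 lower, and all were among the 103, including the 9 oligodendrocyte genes. Of 43 calls taken by the naming rule 16 stayed, those of Aldh1a1, Apod, Cd93, Cldn11, Fth1, Hapln2, Hoxa7, Ier5, Mal, Mbp, Mobp, Padi2, Pdlim2, Ptgds, Slc6a20a and Spp1. Among those that ended, the log2 fold change with the covariate was -0.56 for Cldn5 (adjusted p = 0.117), -0.29 for Cdh5 (0.271), -1.08 for Slc22a2 (0.245), -0.54 for Itih2 (0.0785), -0.35 for Aldh1a2 (0.228) and 0.37 for Rtkn2 (0.619). The 103 calls fell to 24 without WT replicate 1 and 22 without h1 replicate 2 and rose to 166 without WT replicate 3, of which 97 were lower, so that most calls were then falls. Of the genes named here only Aldh1a1, Cd93, Cldn11, Hapln2, Itih2, Mal, Mbp, Mobp, Ptgds and Slc6a20a were called in each of the 12 leave-outs. Over these leave-outs 6 to 11 oligodendrocyte genes rose, and without h1 replicate 2 no retinoid or meningeal gene fell. The endothelial and mural genes that fell numbered 0 without WT replicate 1 and 1 without WT replicate 3, h1 replicate 2 or h1 replicate 3, and no oligodendrocyte precursor gene rose without WT replicate 1 or h1 replicate 2.

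In h2 brains, 10 of 20 protein folding stress genes were lower than in WT. Hspa5, the chaperone BiP, stood at 257 CPM against 364 in WT, and Pdia4, a protein disulfide isomerase, fell by 0.47 on the log2 scale (SE 0.07, n = 3 per group, adjusted p = 0.00642). The secreted factor Manf fell by 0.41, the transcription factor Xbp1 by 0.43 and Herpud1 by 0.27. The inducible heat shock genes Hspa1a (-0.53) and Hspa1b (-0.67) fell as well. The solute carrier Slc6a20a rose by 0.55 (SE 0.06, adjusted p = 5.04e-05), from 22.95 to 33.6 CPM, and Slc22a2 fell by 1.55 on the log2 scale (SE 0.27, adjusted p = 0.0047).

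In all, 112 genes were called in h2, 56 higher and 56 lower, with a median fold of 1.23, and DESeq2 called 52 higher and 81 lower. Of the 112, 11 changed more than 2-fold and 9 without a usable symbol are not named. The libraries of all 112 did not overlap, against 15.6% of all genes tested and 10% by chance. The largest rises by the naming rule were Spaar (1.36), Fam180a (1.28), Tmprss5 (1.01), Accs (0.60), Serpinb1a (0.60), Slc6a20a, Aebp1 (0.55), Serpind1 (0.48), Tmem125 (0.48) and Opalin (0.45). Fam180a went from 1.55 to 3.79 CPM (SE 0.18, adjusted p = 0.000346) and Serpinb1a from 13.5 to 20.4 CPM (SE 0.08, adjusted p = 0.000178). The largest falls were Slc22a2, Fas (-0.92), Prr5 (-0.80), Itih2 (-0.79), Acer2 (-0.67), Hspa1b, Sdf2l1 (-0.67), Banp (-0.58), Hspa1a and Cables1 (-0.51). Itih2 went from 13.5 to 7.78 CPM (SE 0.11, adjusted p = 0.000303), Fas, a death receptor, from 2.30 to 1.199 CPM and Banp from 29.5 to 19.6 CPM.

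Of 20 protein folding stress genes in h2, 10 fell, none rose and 10 did not pass, and 15 fell when adjusted over the list alone. The camera adjusted p was 1.83e-19 and the fry adjusted p was 0.0214, and the adjusted p was 0.141 with an estimated correlation. Of 16 oligodendrocyte genes, 3 rose (Opalin, Gjb1 at 0.35 and Mbp at 0.17), none fell and 13 did not pass, and 12 rose when adjusted over the list alone (camera adjusted p = 8.21e-13, adjusted p = 0.411 with an estimated correlation). Of 18 choroid plexus genes Kl (0.37) rose and none fell, with 3 higher when adjusted over the list alone (camera adjusted p = 0.00576, adjusted p = 0.702 with an estimated correlation). Of 16 meningeal genes Aebp1 rose and none fell, with 2 higher and 1 lower when adjusted over the list alone (camera adjusted p = 0.0151, adjusted p = 0.433 with an estimated correlation). Lists that passed with no called member were circadian (camera adjusted p = 0.000353), glucocorticoid-responsive (0.000255) and monoamine and cholinergic genes (0.00236), all down, and mitochondrially encoded genes (1.51e-05), up. Their adjusted p were 0.411, 0.582, 0.411 and 0.582 with an estimated correlation, and adjusted over the list alone 0, 2 and 4 members of the 3 down lists were lower and 2 mitochondrially encoded genes were higher.

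Within 20 Mb of Tyr, 2 of 253 genes were called in h2 (odds ratio 1.16, Fisher's exact p = 0.692). The Xist covariate left 70 genes called in h2, 41 higher and 29 lower, 53 of them among the 112, and 5 of the protein folding stress genes fell. Of 38 calls taken by the naming rule 22 stayed, and those of Accs, Acer2, Acss2, Apod, Cables1, Fth1, Gjb1, Hspa1a, Hspa1b, Mbp, Rims4, Sbk1, Sdf2l1, Serpind1, Spaar and Stox2 ended, with log2 fold changes of -0.44 for Hspa1a (adjusted p = 0.164) and 1.22 for Spaar (0.104). The 112 calls fell to 18 without WT replicate 1, 25 without WT replicate 2, 45 without h2 replicate 1 (32 higher) and 27 without h2 replicate 2, and rose to 348 without WT replicate 3 (226 lower). Of the genes named here only Aebp1, Banp, Fam180a, Itih2, Serpinb1a, Slc22a2 and Slc6a20a were called in each leave-out, and the protein folding genes that fell numbered 0 without WT replicate 1, 1 without WT replicate 2, 3 without h2 replicate 1, 2 without h2 replicate 2 and at most 10. The oligodendrocyte genes that rose numbered 0 without WT replicate 1, WT replicate 2 or h2 replicate 2 and 10 without WT replicate 3.

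In h4 brains, 6 of 16 astrocyte genes were higher than in WT, and 6 of 26 synaptic vesicle and glutamate receptor genes and 5 of 26 voltage-gated channel genes were lower. Grin2b, a subunit of NMDA receptors, fell by 0.49 on the log2 scale (SE 0.06, n = 3 per group, adjusted p = 0.000782), from 441 to 314 CPM. Cacna1i, a T-type calcium channel, fell by 0.43 (SE 0.04, adjusted p = 1.05e-06) and Cacna1a, a P/Q-type calcium channel, by 0.34. The astrocyte genes S100b (0.28), Aldh1l1 (0.28), Gfap (0.38) and Slc1a3 (0.15) rose. Fabp7, a fatty acid binding protein of radial glia and astrocytes, rose by 0.82 (SE 0.12, adjusted p = 0.00484), from 42.1 ± 1.504 to 74.5 ± 7.08 CPM (SD, n = 3).

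In all, 751 genes were called in h4, 271 higher and 480 lower, with a median fold of 1.16, and DESeq2 called 189 higher and 536 lower. Only 20 changed more than 2-fold, and 36 without a usable symbol are not named. For 720 of the 751 the libraries did not overlap, against 21.2% of all genes tested and 10% by chance. The largest rises by the naming rule were H2-Q1 (2.04), Aox4 (1.52), Fam180a (1.28), Atf3 (from 0.705 to 1.67 CPM), Msln (1.18), Exoc3l4 (0.88), Abhd12b (0.84), Mmp19 (0.84), Fabp7 and Tmprss5 (0.80). H2-Q1, an MHC class I gene with close copies, went from 0.401 to 1.65 CPM (SE 0.31, adjusted p = 0.000169), and the aldehyde oxidase Aox4 from 0.939 to 2.69 CPM (SE 0.26, adjusted p = 0.000661). Besides Rorb, the largest falls included Egfl6 (-1.53), Slc22a2 (-1.44), Pdzph1 (-1.12), Aspg (-0.87), Ccdc18 (-0.85), Ppp1r3g (-0.84), Tfcp2l1 (-0.75) and Pla2g4b (-0.70). Egfl6 went from 2.82 to 0.972 CPM (SE 0.24, adjusted p = 0.00021).

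Of 26 synaptic vesicle and glutamate receptor genes in h4, 6 fell, including Grin2b, the syntaxin Stx1a (-0.25), the scaffold Dlg4 (-0.19) and Camk2a (-0.17). None rose, 20 did not pass, and 11 fell when adjusted over the list alone (camera adjusted p = 1.17e-07, fry adjusted p = 0.00961, adjusted p = 0.179 with an estimated correlation). Of 26 voltage-gated channel genes 5 fell, including Cacna1i, Cacna1a and Scn8a (-0.20), none rose and 21 did not pass, and 7 fell when adjusted over the list alone. Their camera adjusted p was 1.69e-07, and the adjusted p was 0.292 with an estimated correlation. Of 16 astrocyte genes 6 rose, none fell and 10 did not pass, with 6 higher and 1 lower when adjusted over the list alone (camera adjusted p = 8.62e-06, fry adjusted p = 0.00961, adjusted p = 0.179 with an estimated correlation). Of 16 meningeal fibroblast genes Aebp1 (0.62), Ogn (0.45), Col3a1 (0.38) and Bgn (0.27) rose, none fell and 12 did not pass, with 6 higher and 1 lower when adjusted over the list alone (camera adjusted p = 0.000198, adjusted p = 0.235 with an estimated correlation).

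Of the 20 protein folding stress genes in h4, 3 fell, Atf4 (-0.28), Calr (-0.17) and Hsp90b1 (-0.14), and none rose, with 8 lower when adjusted over the list alone (camera adjusted p = 3e-06, adjusted p = 0.335 with an estimated correlation). Of 23 immediate early genes Jun (0.25) alone was called, while the list's median log2 fold change was 0.51 and 6 were higher and 1 lower when adjusted over the list alone. The camera adjusted p was 1.17e-07, and the adjusted p was 0.388 with an estimated correlation. Fos stood at 48.9 ± 12.1 CPM in h4 against 24.7 ± 4.88 in WT (SD, n = 3, adjusted p = 0.241). Opalin (0.31) was the 1 oligodendrocyte gene that rose, with 8 higher when adjusted over the list alone (camera adjusted p = 4.67e-06, adjusted p = 0.437 with an estimated correlation). Of 13 mitochondrially encoded genes mt-Atp6 (0.13) and mt-Cytb (0.10) rose, with 4 higher when adjusted over the list alone and the same camera and estimated-correlation p. Among layer markers of the cortex, Bcl11b (-0.21) fell in the layer 5 list (5 lower when adjusted over the list alone, camera adjusted p = 0.00374, adjusted p = 0.335 with an estimated correlation).

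The other lists with calls in h4 did not pass camera. In the layer 4 list, whose neurons express Rorb, Btbd3 (0.13) rose, none fell and 13 of 14 did not pass, with 2 higher when adjusted over the list alone (camera adjusted p = 0.605). No layer 4 gene was called in h1 or h2. Rasgrf2 (-0.14) fell in the layer 2/3 list, Tbr1 (-0.19) in the layer 6 list, Foxp1 (-0.17) in the striatal list and Itpr1 (-0.21) in the cerebellar list. Fabp7 and Eomes (0.73) rose in the olfactory bulb list, Kl (0.25) in the choroid plexus list, and Myh11 (0.36) and Vtn (0.21) in the endothelial and mural list. Hlf (-0.18) and Npas2 (-0.26) fell in the circadian list and Irak2 (-0.34) in the interleukin 1 list, where Il1rap (0.23) had risen in h1 (camera adjusted p = 0.316 in h1, 1 higher when adjusted over the list alone). Aldh1a1 (0.42) rose in the retinoid list. Camera adjusted p of these 10 lists, layer 4 aside, lay between 0.18 and 0.971, and counts adjusted over the list alone were the same except for 4 higher endothelial and mural genes and 1 lower olfactory bulb gene. For the cerebellar list (median 0.022, camera down) and the endothelial and mural list (median -0.003, camera up) the median and the test differed in sign.

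Within 10 Mb of Il1r1, 10 of 89 genes were called in h4 (11.2%) against 4.55% elsewhere, an odds ratio of 2.65 (95% interval 1.22 to 5.17, Fisher's exact adjusted p = 0.0226). Within the 20 Mb window fixed beforehand, 15 of 178 were called (odds ratio 1.93, adjusted p = 0.0829). The 10 Mb window did not pass between h4 and h1 (odds ratio 1.48, adjusted p = 0.72) or h2 (1.41, adjusted p = 0.799). Of 29 measured genes in the list of Il1r1 neighbours, Tgfbrap1 (-0.22), Lonrf2 (-0.15) and Npas2 fell and none rose, with 3 lower when adjusted over the list alone (camera adjusted p = 0.145). Of the 20 measured neighbours of Rorb on chromosome 19, Aldh1a1 rose and Gnaq (-0.15) fell, with the same numbers when adjusted over the list alone (camera adjusted p = 0.413). With Xist, high in 2 of 3 h4 libraries, as a covariate, 617 genes were called, 567 of them among the 751, without Rorb, Acss2, Myh11, Rasgrf2, Sbk1, Tbr1, Vtn and mt-Cytb among those named, and 3 channel genes fell. The 751 calls fell to 230 without WT replicate 1, 294 without WT replicate 2, 320 without h4 replicate 1 and 422 without h4 replicate 3, and a total of 31 of the 73 calls taken by the naming rule were made in every leave-out, among them Aox4, Cacna1a, Cacna1i, Egfl6, Fabp7, Gfap, Grin2b, Il1r1, S100b and Slc22a2. In the same leave-outs the synaptic genes that fell numbered 3 without WT replicate 1, WT replicate 2 or h4 replicate 1 and 9 without WT replicate 3. The channel genes that fell numbered 2 without WT replicate 1, 3 without WT replicate 2 or h4 replicate 1 and 10 without WT replicate 3, and the protein folding genes 1 without WT replicate 1 or h4 replicate 1, 7 without h4 replicate 2 and 9 without WT replicate 3. Astrocyte genes that rose numbered 4 to 6, meningeal genes 2 without WT replicate 1 or h4 replicate 1, oligodendrocyte genes 8 without WT replicate 3 and 0 without WT replicate 1, WT replicate 2, h1 replicate 3, h2 replicate 2 or h4 replicate 3, and immediate early genes 6 without h2 replicate 1 and 0 without WT replicate 1. Without h4 replicate 2, 6 striatal genes fell and 3 cerebellar genes rose, and the fall of 1 layer 5 gene was lost without WT replicate 1, WT replicate 2, h4 replicate 1 or h4 replicate 3.

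**Figure D2:**
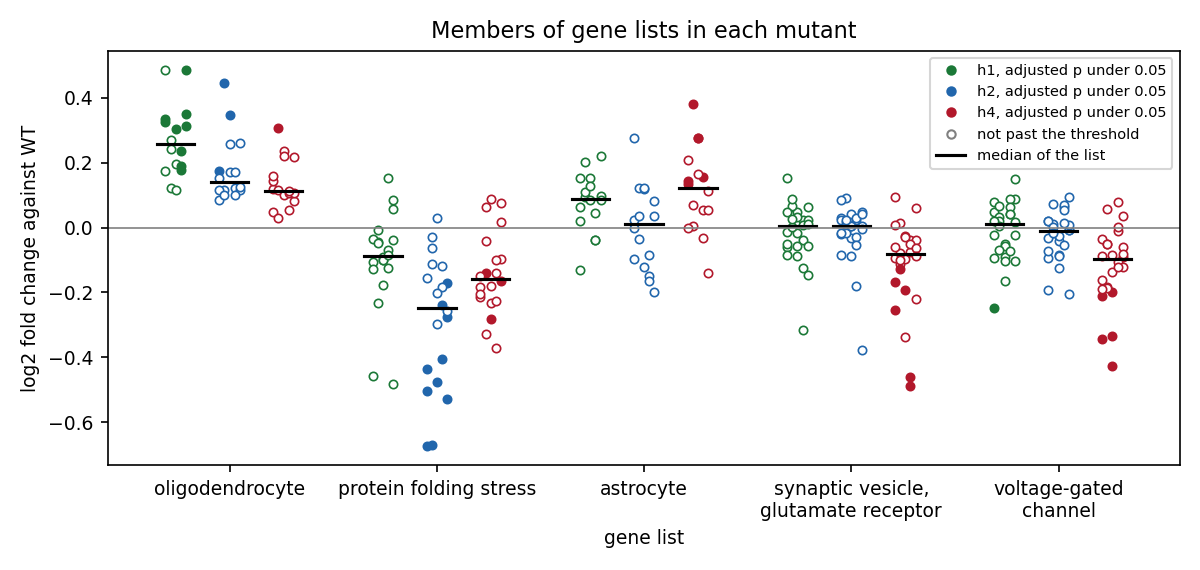
Log2 fold change against WT of each measured member of 5 gene lists in h1, h2 and h4, with filled points for an edgeR adjusted p under 0.05 and a black line at the median. In h1, 9 of 16 oligodendrocyte genes are filled and higher, in h2, 10 of 20 protein folding stress genes are filled and lower, and in h4, 6 of 16 astrocyte genes are filled and higher.

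Direct comparison of h2 with h1 gave 119 calls, 31 higher and 88 lower in h2, while DESeq2 called 153 with 24 higher. The circadian genes Dbp (-0.43), Ciart (-0.57), Tef (-0.22) and Nr1d2 (-0.32) were lower in h2 than in h1. Cldn5 was higher in h2 by 0.81 (SE 0.10, n = 3 per group, adjusted p = 0.00107), at 36.0 against 20.4 CPM. Map3k6 was lower by a log2 fold change of -1.26 (SE 0.20, adjusted p = 0.00352), at 2.22 against 5.20 CPM. The other largest rises were Gbp4 (1.09), Aplnr (1.06), Lrrc32 (0.82) and Slc38a5 (0.78), and the other largest falls Fmo2 (-1.03), Mc4r (-1.01), Nostrin (-0.90) and Nrros (-0.88). Of all genes tested 15.5% did not overlap between the libraries of h1 and h2, with 10% by chance, and all 119 called genes did not.

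Of 20 circadian genes 5 were lower in h2 than in h1, none was higher and 15 did not pass, with 2 higher and 10 lower when adjusted over the list alone (camera adjusted p = 2.42e-08, adjusted p = 0.115 with an estimated correlation). Of 12 glucocorticoid-responsive genes Map3k6 alone was called, but 10 were lower when adjusted over the list alone and the median log2 fold change was -0.88. The camera adjusted p was 9.66e-26, and the adjusted p was 0.0699 with an estimated correlation. Herpud1 (-0.33) and Pdia4 (-0.38) were the called protein folding stress genes, with 1 higher and 9 lower when adjusted over the list alone (camera adjusted p = 3.58e-10, adjusted p = 0.156 with an estimated correlation). Mobp (-0.23) and Mal (-0.21) were lower among oligodendrocyte genes (1 higher and 8 lower when adjusted over the list alone, camera adjusted p = 1.75e-05, adjusted p = 0.453 with an estimated correlation). Olig2 (-0.29) and Pdgfra (-0.18) were lower among oligodendrocyte precursor genes (1 higher and 3 lower when adjusted over the list alone, camera adjusted p = 0.00797, adjusted p = 0.384 with an estimated correlation). Cldn5 and Pdgfrb (0.38) were higher among endothelial and mural genes (7 higher and 1 lower when adjusted over the list alone, camera adjusted p = 0.000143, adjusted p = 0.362 with an estimated correlation). The immediate early and meningeal lists, up, and the astrocyte list, down, had no call (camera adjusted p = 4.91e-07, 2.22e-05 and 0.000363, adjusted p = 0.384, 0.131 and 0.156 with an estimated correlation), and adjusted over the list alone 1 and 2 members were higher and 3 lower. Ccn2 (-0.34) in the layer 6 list, Kcnn2 (-0.36) in the channel list and Klf9 (-0.41) among the neighbours of Rorb were lower, with 2, 1 and 3 lower when adjusted over the list alone (camera adjusted p = 0.498, 0.971 and 0.148). Xist was high in 1 of 3 libraries of both groups, and with Xist as a covariate 131 genes were called, 112 of them among the 119, without Mal among those named. The count fell to 45 without h1 replicate 2, 44 without h2 replicate 1 and 66 without h2 replicate 2, and Aplnr, Cldn5, Dbp, Herpud1, Map3k6 and Nrros were called in every leave-out. The circadian genes that were lower numbered 2 without h1 replicate 2 and 4 to 6 in the other leave-outs. Protein folding genes that were lower ranged from 1 to 6, the latter without WT replicate 3, and oligodendrocyte genes from 0, without h2 replicate 1, to 4, without WT replicate 1 or WT replicate 3.

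Between h4 and h1, 765 genes were called, 348 higher and 417 lower in h4 (DESeq2 241 and 462). Of 23 immediate early genes, which respond to neuronal activity, 5 were higher in h4, with Arc at 157 ± 19.9 against 52.7 ± 9.99 CPM (SD, n = 3), a log2 fold change of 1.58 (SE 0.27, adjusted p = 0.017). Npas4 (1.58), Nr4a3 (1.14), Fosl2 (0.75) and Jun (0.20) were also higher, and 7 of 16 oligodendrocyte genes, Mbp and Mobp among them, were lower. The other largest rises were Aox4 (1.43) and Fabp7 (1.17), and besides Rorb the largest falls were Egfl6 (-1.57), Pdzph1 (-1.30), Il12rb1 (-1.23) and Cort (-1.22). The libraries of 755 of the 765 did not overlap, against 24.1% of all genes tested and 10% by chance.

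Of the immediate early genes none was lower and 18 did not pass, with 17 higher when adjusted over the list alone (camera adjusted p = 1.36e-17, adjusted p = 0.193 with an estimated correlation). Of 16 oligodendrocyte genes 7 were lower and 9 did not pass, with 9 lower when adjusted over the list alone (camera adjusted p = 1.21e-06, adjusted p = 0.394 with an estimated correlation). Of 20 interferon and MHC genes 5 were higher, among them Irf9 (0.34), Ifit1 (0.63) and B2m (0.17), with 6 higher when adjusted over the list alone (camera adjusted p = 1.16e-05, adjusted p = 0.259 with an estimated correlation). In the meningeal list 4 were higher and none lower, with 9 higher when adjusted over the list alone (camera adjusted p = 9.83e-07, adjusted p = 0.193 with an estimated correlation). In the synaptic list 6 and in the channel list 4 were lower and none higher, with 11 and 9 lower when adjusted over the list alone. Their camera adjusted p were 2.99e-07 and 9.83e-07, with adjusted p of 0.193 and 0.259 with an estimated correlation. Of 17 endothelial and mural genes Myh11 (0.47), Itm2a (0.18) and Cldn5 (0.40) were higher, with 8 higher when adjusted over the list alone (camera adjusted p = 0.000281, adjusted p = 0.378 with an estimated correlation). Of 11 layer 5 genes Pcp4 (-0.21) and Deptor (-0.22) were lower, with 5 lower when adjusted over the list alone (camera adjusted p = 0.000281, adjusted p = 0.259 with an estimated correlation). Of 13 oligodendrocyte precursor genes Tmem100 (0.44) was higher and Olig1 (-0.22), Olig2 (-0.27) and Pdgfra (-0.14) were lower, with the same numbers when adjusted over the list alone (camera adjusted p = 0.0321, adjusted p = 0.45 with an estimated correlation). The glucocorticoid-responsive list, down, had no call and 4 lower when adjusted over the list alone (camera adjusted p = 2.67e-08, adjusted p = 0.259 with an estimated correlation). In the striatal list Scn4b (-0.18) and Pde10a (-0.31) were lower, with 3 lower when adjusted over the list alone, and the cerebellar list, up, had none by either count. Their camera adjusted p were 0.0495 and 0.0344, or 0.199 and 0.269 with the Xist covariate, and both had an adjusted p of 0.708 with an estimated correlation.

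Among lists that did not pass camera, Zic1 (0.26) was higher and Slc17a6 (-0.15) lower in h4 than in h1 in the thalamic list, Prox1 (0.19) was higher and Bok (-0.32) lower in the hippocampal list, and Sncg (0.32) was higher in the hindbrain and spinal list (camera adjusted p = 0.807, 0.873 and 0.807). Adjusted over the list alone these counts differed only by 2 higher hippocampal genes. Tbr1 (-0.20) and Rprm (-0.28) in the layer 6 list, Hlf (-0.25) and Tef (-0.16) in the circadian list and Slc5a7 (-0.32) in the monoamine and cholinergic list were lower, and Fabp7 and Eomes (1.03) in the olfactory bulb list were higher (camera adjusted p = 0.179, 0.125, 0.358 and 0.125). Of astrocyte genes Slc1a3 (0.19) and S100b (0.19) were higher and Slc1a2 (-0.24) lower, with 5 higher and 2 lower when adjusted over the list alone (camera adjusted p = 0.125). Hspa1a (0.50) was higher and Atf4 (-0.18) lower in the protein folding stress list, Irak2 (-0.52) was lower in the interleukin 1 list and Tgfbrap1 (-0.27) among the neighbours of Il1r1 (camera adjusted p = 0.101, 0.985 and 0.141). On chromosome 1, which carries Il1r1, 67 of 953 genes were called (7.03% against 4.52% elsewhere, odds ratio 1.60, Fisher's exact adjusted p = 0.0175), while for h4 against WT (odds ratio 1.11, adjusted p = 0.944) and h2 (1.07, adjusted p = 1) chromosome 1 held no such excess.

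Under the Xist covariate 526 genes were called between h4 and h1, 487 of them among the 765, without Nr4a3, Fosl2, Jun, Il12rb1, Ifit1, B2m, Bgn, Cldn5, Pdgfra, Prox1, Rprm, Sncg and Tef among those named, and 2 immediate early and 1 interferon gene were then higher. The count fell to 352 without h1 replicate 2, 340 without h1 replicate 3, 313 without h4 replicate 1 and 382 without h4 replicate 3. The immediate early genes called numbered 0 without h1 replicate 2, h1 replicate 3 or h4 replicate 3, 2 without h4 replicate 1, 3 without h1 replicate 1, WT replicate 2, h2 replicate 2 or h4 replicate 2 and 11 without h2 replicate 1. The interferon genes called numbered 0 without h1 replicate 3, h4 replicate 1 or h4 replicate 3, 1 without h1 replicate 2 and 2 without h1 replicate 1. The oligodendrocyte genes that were lower numbered 2 without h4 replicate 1 and 3 without h1 replicate 2, and up to 9. Synaptic genes numbered 2 without h4 replicate 1 or h4 replicate 3 and 3 without h1 replicate 2 or h1 replicate 3, and channel genes 1 without h1 replicate 2 and 2 without h4 replicate 1 or h4 replicate 2. The meningeal genes that were higher numbered 2 without h1 replicate 3 or h4 replicate 3. Endothelial and mural genes numbered 0 without h1 replicate 2, 1 without h1 replicate 3 or h4 replicate 3 and 5 without WT replicate 3. Without h4 replicate 2, 6 striatal genes were lower and 6 cerebellar genes higher, and no striatal gene was lower without h1 replicate 1 or h4 replicate 3. Layer 5 genes numbered 0 to 4, and the oligodendrocyte precursor genes that were lower 0 without h1 replicate 3 or h4 replicate 1. By contrast Aox4, Cacna1i, Egfl6, Fabp7, Grin2b, Mbp, Mobp, Pdzph1 and Rorb were called in every leave-out.

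Between h4 and h2, 531 genes were called, 254 higher and 277 lower in h4. Aox4 (1.43), Eomes (1.14), Il1r1 (1.10), Thbs4 (1.06) and Atoh8 (0.98) were the largest rises. Eomes, a transcription factor of intermediate progenitors, stood at 8.30 against 3.66 CPM (SE 0.20, n = 3 per group, adjusted p = 0.00405). Rorb, Egfl6 (-1.61), Pdzph1 (-1.57) and Fxyd3 (-1.46) were among the largest falls. The libraries of 528 of the 531 did not overlap, against 21.6% of all genes tested and 10% by chance. Of 16 astrocyte genes Slc1a3 (0.24), S100b (0.16) and Gfap (0.26) were higher and 13 did not pass, with 9 higher and 1 lower when adjusted over the list alone (camera adjusted p = 5.51e-06, adjusted p = 0.195 with an estimated correlation). Of 26 synaptic genes 5 were lower and 21 did not pass, with 1 higher and 8 lower when adjusted over the list alone (camera adjusted p = 2.87e-07, adjusted p = 0.224 with an estimated correlation). Of 26 channel genes 4 were lower, with 1 higher and 6 lower when adjusted over the list alone (camera adjusted p = 5.17e-06, adjusted p = 0.453 with an estimated correlation). In the protein folding stress list Hspa1a (0.55) and Pdia4 (0.30) were higher and Atf4 (-0.31) was lower in h4 than in h2, with 8 higher and 1 lower when adjusted over the list alone (camera adjusted p = 0.00068, adjusted p = 0.468 with an estimated correlation). In the circadian list Nr1d2 (0.31) was higher and Arntl (-0.29) lower, with 7 higher and 2 lower when adjusted over the list alone (camera adjusted p = 0.00585, adjusted p = 0.453 with an estimated correlation). In the interferon list Ifit1 (0.60) was higher, with 2 higher when adjusted over the list alone (camera adjusted p = 0.00914, adjusted p = 0.468 with an estimated correlation). The immediate early, glucocorticoid-responsive and monoamine and cholinergic lists, all up, had no call, with 0, 0 and 2 higher when adjusted over the list alone. Their camera adjusted p were 2.32e-07, 0.000258 and 0.014, and their adjusted p were 0.453, 0.468 and 0.453 with an estimated correlation. In the striatal list Scn4b (-0.19) was lower, with 3 lower when adjusted over the list alone (camera adjusted p = 0.0162, or 0.103 with the Xist covariate, and adjusted p = 0.694 with an estimated correlation). C1qc (0.25) was higher in the microglial list, Atp5j2 (0.19) in the nuclear oxidative phosphorylation list and Col3a1 (0.31) in the meningeal list, none of which passed camera (adjusted p = 0.974, 0.69 and 0.134). Bok (-0.28) was lower in the hippocampal list, Cldn5 (-0.41) in the endothelial and mural list, Irak2 (-0.35) in the interleukin 1 list and Tgfbrap1 (-0.28) among the neighbours of Il1r1, and Aldh1a1 (0.25) was higher in the retinoid list (camera adjusted p = 0.852, 0.852, 0.69, 0.178 and 0.933). Fitted with Xist as a covariate, 436 genes were called, 389 of them among the 531, without Bok, C1qc, Cldn5, Gfap, Ifit1 and Pdia4 among those named. The count of 531 fell to 312 without h2 replicate 1, 258 without h2 replicate 2, 251 without h4 replicate 1 and 346 without h4 replicate 3, and without h2 replicate 2 or h4 replicate 3 most calls were rises (136 and 174). Astrocyte genes that were higher numbered 1 without h2 replicate 1, h2 replicate 2, h4 replicate 1 or h4 replicate 3. Synaptic genes that were lower numbered 2 without h2 replicate 1 and 3 without h2 replicate 2, h4 replicate 1 or h4 replicate 3, and channel genes 2 without h2 replicate 2 or h4 replicate 1. Without h4 replicate 2, 5 striatal genes were lower and 3 cerebellar genes higher, and no striatal gene was lower without h2 replicate 1, h2 replicate 2, h4 replicate 1 or h4 replicate 3. Protein folding genes that were higher ranged from 0, without h2 replicate 1, to 4, without WT replicate 3.

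The mean of the 3 mutants against WT gave 181 calls, 80 higher and 101 lower (DESeq2 80 and 181). Fam180a (1.11, adjusted p = 0.000312), Tmprss5 (0.82), Slc6a20a (0.50, adjusted p = 7.63e-06), Aebp1 (0.49, adjusted p = 7.68e-06), Accs (0.49) and Ptgds (0.41, adjusted p = 7.68e-06) were the largest rises. Slc22a2 (-1.43, adjusted p = 0.000349), Itih2 (-0.64, adjusted p = 0.000185), Aldh1a2 (-0.38) and Robo3 (-0.36) were the largest falls. Of 16 oligodendrocyte genes 10 were higher, none was lower and 6 did not pass, with 14 higher when adjusted over the list alone (camera adjusted p = 5.99e-20, adjusted p = 0.209 with an estimated correlation). Of 20 protein folding stress genes Manf and Xbp1 were lower, with 15 lower when adjusted over the list alone (camera adjusted p = 2.89e-14, adjusted p = 0.209 with an estimated correlation). The mitochondrially encoded list with mt-Atp6 (0.08) called, the astrocyte list with S100b (0.16), Aldh1l1 (0.18) and Gfap (0.23), and the choroid plexus list with Kl (0.28) were up, with 3, 3 and 2 higher when adjusted over the list alone. Their camera adjusted p were 2.37e-07, 0.000812 and 0.0198, and their adjusted p were 0.534, 0.217 and 0.574 with an estimated correlation. In the channel list Cacna1i (-0.22), Cacna1a (-0.20) and Cacna1g (-0.20) and in the synaptic list Dlg4 (-0.12) were lower, with 4 lower in both when adjusted over the list alone (camera adjusted p = 0.00352 and 0.00373, adjusted p = 0.534 for both with an estimated correlation). In the meningeal list Aebp1 and Ogn (0.30) were higher and Aldh1a2 was lower, with 3 higher and 2 lower when adjusted over the list alone (camera adjusted p = 0.0262, adjusted p = 0.534 with an estimated correlation). For 84 of the 181 genes no mutant library overlapped a WT library, as for 1.92% of all genes tested. Xist was high in 3 of 3 WT and 4 of 9 mutant libraries, and with Xist as a covariate 63 genes were called, 40 higher and 23 lower, 58 of them among the 181. Most calls were then rises, as among Xist-high libraries (42 and 34). Of 20 calls among the largest changes 9 stayed with the covariate, and those of Accs, Tmprss5, Aldh1a2 and Robo3 ended. Of the list members named here Manf, Xbp1, mt-Atp6, Gfap, Cacna1a, Cacna1g, Dlg4 and Ogn lost their call too, and 4 oligodendrocyte genes were called as higher. With the covariate the log2 fold change was -0.285 for Manf (-0.252 without it) and -0.263 for Xbp1 (-0.248 without it). It was 0.078 for mt-Atp6, 0.242 for Gfap, -0.1685 for Cacna1a, -0.156 for Cacna1g, -0.120 for Dlg4 and 0.2225 for Ogn. The count fell to 18 without WT replicate 1, 38 without WT replicate 2 and 105 without h1 replicate 2, and rose to 505, of which 376 were lower, without WT replicate 3. The oligodendrocyte genes that were higher numbered 1 without WT replicate 1 or WT replicate 2, 6 without h1 replicate 1, h1 replicate 3, h2 replicate 2 or h4 replicate 3 and up to 13. Protein folding genes that were lower numbered 0 without WT replicate 1 or WT replicate 2, 6 without WT replicate 3 and 7 without h4 replicate 2, and the 3 astrocyte calls fell to 0 without WT replicate 1 and 1 without WT replicate 2 or WT replicate 3. Channel genes that were lower numbered 1 without WT replicate 1 or WT replicate 2 and 7 without WT replicate 3.

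**Figure D3:**
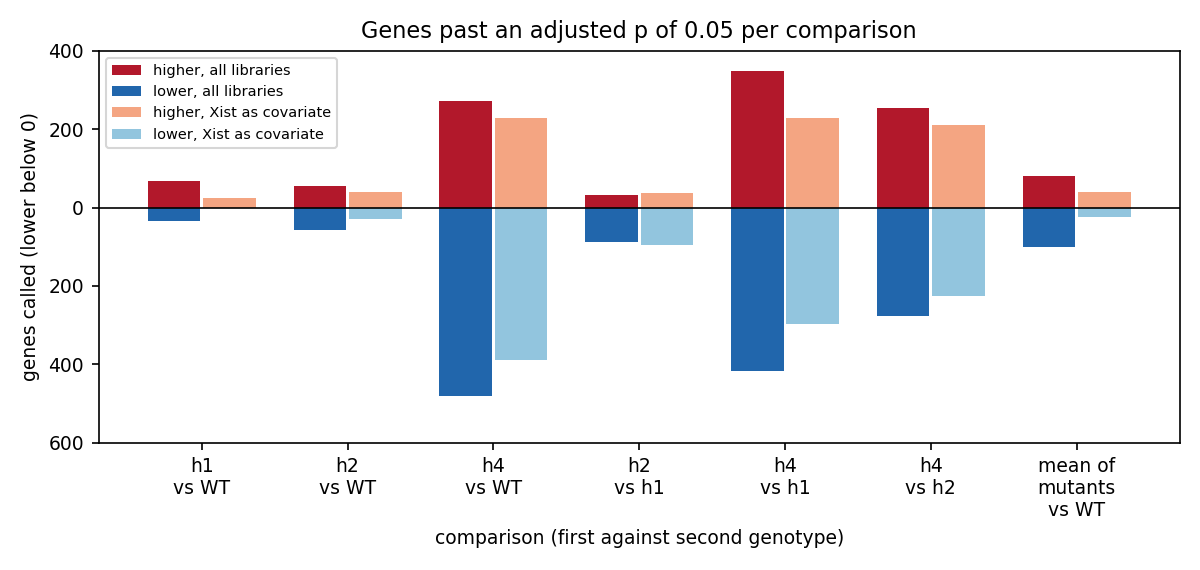
Number of genes called higher (above 0) and lower (below 0) in each of the 7 comparisons, in dark bars for all 12 libraries and in light bars with Xist as a covariate. The comparisons with h4 have 531 to 765 calls, and h1 against WT has 103, or 27 with the covariate.

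A total of 15 genes were called in the same direction in h1, h2 and h4 against WT. Those that rose were Ptgds (0.38, 0.34 and 0.51 in h1, h2 and h4), Slc6a20a (0.43, 0.55 and 0.53), Aebp1 (0.32, 0.55 and 0.62), Spp1 (0.35, 0.27 and 0.40), Apod (0.26, 0.20 and 0.22), Padi2 (0.23, 0.24 and 0.22), Fth1 (0.22, 0.16 and 0.18), Acss2 (0.17, 0.17 and 0.13), H2-Q1 (1.71, 1.97 and 2.04) and Hoxa7 (1.77, 1.88 and 1.86). Those that fell were Slc22a2 (-1.31, -1.55 and -1.44), Itih2 (-0.61, -0.79 and -0.50), Rims4 (-0.20, -0.21 and -0.25), Sbk1 (-0.18, -0.18 and -0.15) and Stox2 (-0.17, -0.16 and -0.20). Hoxa7 was near the detection limit, at 0.239 CPM in WT and 0.829, 0.850 and 0.880 in h1, h2 and h4. These values lie under the 1 CPM asked of genes named by size of change. With Xist as a covariate 5 genes were shared, Ptgds, Slc6a20a, Spp1, Padi2 and Hoxa7, all higher. The other 10, all 5 shared falls among them, lost their call in at least 1 mutant, and for H2-Q1, Aebp1, Itih2 and Slc22a2 that was h1 alone (adjusted p = 0.0636, 0.0805, 0.0785 and 0.245).

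The 3 comparisons share the WT libraries, whose chance values enter each of them. Of the calls, h1 and h2 shared 18 higher and 7 lower, h1 and h4 13 and 8, and h2 and h4 26 and 19 with 1 in opposite directions. With Xist as a covariate these counts were 8 and 0, 9 and 0, and 23 and 6, so h1 then shared no fall with h2 or h4. Independent lists of the sizes without the covariate would share 0.234 and 0.115, 1.13 and 0.990, and 0.920 and 1.63. Unchanged groups simulated against shared controls had a mean of at most 0.3 calls in 20 simulations, too few to give a shared count to set beside these. Across genes, which are not independent replicates, the Pearson correlation of log2 fold changes was 0.675 for h1 and h2, 0.602 for h1 and h4 and 0.612 for h2 and h4, against 0.502, 0.496 and 0.495 in the simulations. The covariances were 0.0583, 0.0553 and 0.0550 against simulated 0.0164, 0.0164 and 0.0165, differences of 0.0419, 0.0388 and 0.0385. Without genes of the X and Y chromosomes the correlations were 0.596, 0.519 and 0.508 against 0.502, 0.496 and 0.492 in the simulations, whose highest values were 0.539, 0.522 and 0.542, so those of h4 with h1 and with h2 lay within the simulated range. The covariances were then 0.0391, 0.0385 and 0.0356 against simulated 0.0161, 0.0161 and 0.0161, differences of 0.0230, 0.0223 and 0.0195. With 3 WT libraries a split would leave 1 part with a single control, so they were not split, and part of the excess overlap may come from the shared controls.

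Over the 7 comparisons, lists with only 1 or 2 called members occurred 83 times, and in 49 of these the list had no call in at least 1 leave-out. Of the 39 lists, 8 had no called member in any of the 7 comparisons. They were blood, hypothalamic peptide, interneuron, pineal and photoreceptor, pituitary, ribosomal protein, sex-linked and suprachiasmatic genes, of which the hypothalamic list passed camera for h2 against h1 (adjusted p = 0.00797, adjusted p = 0.385 with an estimated correlation). Among interneuron genes Gad1 stood at 396, 403, 399 and 421 CPM in WT, h1, h2 and h4, and among ribosomal protein genes Rpl3 at 408, 433, 426 and 404 CPM. In each mutant against WT none of the called lists held with an estimated correlation, the smallest adjusted p being 0.167 in h1, 0.141 in h2 and 0.179 in h4. Scaling by DESeq2 size factors moved the median log2 fold change of all genes by less than 0.01 in every comparison of 2 groups.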

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

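The tests of Rorb in h4, of the WT values behind the oligodendrocyte genes, and of the Il1r1 segment, the Xist composition and the depth of h4 against the other mutants behind the h4 count were chosen only after the results they measure were seen.

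For 22 differences in 17 of the 63 genes looked at, a direct test between 2 mutants passed while the effects against WT had opposite signs, with at least 1 of them called. The smaller effect ran in size from 0.017 (Hspa1a, h4) to 0.70 (Rorb, h2, not called), so opposite changes are not implied. Values are log2 fold changes by edgeR. In h2 against h1 these were Id1 (-0.70), Pnpla2 (-0.60), Cables1 (-0.63), Cldn5 (0.81) and Mmp14 (0.55). In h4 against h1 they were Rorb (-1.60), Mmp14 (0.53), Klf10 (0.54), Mmp19 (1.03), Fabp7 (1.17), Egfl6 (-1.57), Pdzph1 (-1.30), Ppp1r3g (-0.93) and Tfcp2l1 (-0.87). In h4 against h2 they were Rorb (-1.68), Il1r1 (1.10), Fas (0.97), Acer2 (0.89), Hspa1a (0.55), Fabp7 (0.95), Egfl6 (-1.61) and Pdzph1 (-1.57).

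Rorb was lower in h4 than in WT. The uneven Xist composition was argued against as the whole cause, since among libraries with high Xist alone the log2 fold change was -0.98 (SE 0.0963). The ratio of h4 to WT was 0.967 for mean length, 0.507 for CPM and 0.514 for TPM, which allows for length. This argues against a shift in transcript length as the whole cause. A change of the whole region was argued against by a median log2 fold change of 0.0538 over 20 neighbouring genes, 1 of which fell. The h4 allele of Rorb, the h4 background strain and the order of the libraries may each account for the difference and were not tested.

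Oligodendrocyte genes were higher in h1 than in WT, with a median log2 fold change of 0.256 over 16 genes. The median was 0.264 with Xist as a covariate, where the 9 called genes stayed called, and 0.258 with a gene length offset, which argues against the Xist composition and a length trend as the whole cause. Low values in the WT libraries alone would leave h1 and h4 alike, but 7 members were lower in h4 than in h1, where the test asked for 4. That number was 2 without h4 replicate 1 and 3 without h1 replicate 2, and only 2 members were lower in h2 than in h1, or 0 without h2 replicate 1, so low WT values may play a part and are argued against only as the whole cause. The h1 allele and differences in dissection or handling between groups may still account for it, and with an estimated correlation the list did not pass.

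The count of 751 genes called in h4 against WT was larger than 103 in h1 and 112 in h2. After every library was thinned to the smallest library total, 74.3 percent of the calls were kept, just under the 3 in 4 set beforehand, so a part played by depth in single calls stays open. At those equal totals 628 genes were called in h4, 99 in h1 and 108 in h2, and the ratio of 5.81 to the larger of the other counts argues against depth as the reason for the larger count. Within 40 Mb of Il1r1 lay 2.93 percent of the calls, which argues against a linked segment as the main cause, and 75.5 percent of the calls were kept with Xist as a covariate, which argues against the Xist composition as the whole cause. The allele, the strain background with any linked segment, and the library order follow the group and cannot be told apart, and any of them may contribute.

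Other splits of the libraries were fitted in the same way. For 6 libraries there are 10 splits, which cannot give a share under 0.05, and in each comparison of 2 groups only 1 split, the real one, reached the real count. The real counts and the highest of the other splits were 103 and 0 for h1 against WT, 112 and 3 for h2 against WT, 751 and 39 for h4 against WT, 119 and 2 for h2 against h1, 765 and 1 for h4 against h1, and 531 and 1 for h4 against h2. For the mean of mutants, 2 of 100 splits reached 181, the real one included. In 2 other splits the WT libraries stayed together and only the mutants were regrouped, and these gave 38 and 27 calls. The count thus depends on how the mutants are grouped, and the share of splits does not by itself test WT against mutants. The highest other split, with 919 calls, set the h4 libraries apart, which points to a structure of the samples.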

How the results depend on the processing

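The fit to the 7 libraries with high Xist was chosen after seeing the data, and the other alternatives were set earlier. Over all results, the stricter filter kept each direction and side of the threshold in 328 of 328, the DESeq2 size factors in 321 and the length offset in 307, while limma on log2 TPM weakened 228, the Xist-high fit 187 and the Xist covariate 84. Fewer libraries in the Xist-high fit and fewer degrees of freedom with the covariate, or with only the groups compared for a pair of genotypes, are part of their construction. For the mean of mutants the model of only the groups compared kept all 12 libraries. It merged the 9 mutant libraries into 1 group, so differences between mutants entered its spread. For the other changes below the cause was not tested. At these totals, with 3 mice per group and the spread between them, 90 percent of simulated 1.5-fold changes and 56 percent of the smaller simulated ones were recovered for h1 against WT, which does not part depth from spread. On depth itself, 74.3 percent of the h4 calls were kept after thinning every library to the smallest total.

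Counts of called genes moved over 1.5 times as follows. With no low-count filter 236 genes were called for h1 against WT, 288 for h2 against WT, 290 for h2 against h1, 844 for h4 against h2 and 373 for the mean of mutants, with 40 shared calls. With limma on log2 TPM the counts were 0 for h1 against WT (1360 genes at an unadjusted p under 0.05, while DESeq2 called 130), 11 for h2 and 152 for h4 against WT, 4 for h2 against h1, 105 for h4 against h1, 118 for h4 against h2 and 8 for the mean, with 0 shared calls. With the Xist covariate they were 27 for h1, 70 for h2 and 63 for the mean against WT, with 5 shared calls. In the Xist-high fit h1 and h2 hold 1 library each and h4 holds 2, so a lone library is assumed to vary like the other groups, and its counts describe those mice. Among Xist-high libraries they were 16 for h1, 39 for h2 and 76 for the mean against WT, 23 for h2 against h1, 116 for h4 against h1 and 127 for h4 against h2, with 2 shared calls and 13 lists passing camera for h2 against WT. With only the groups compared they were 193 for h2 against h1 and 22 for the mean, where the mutants were merged into 1 group. The count of 181 for the mean thus depends on fitting the mutants as separate groups.

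The log2 fold change of Rorb passed with DESeq2 in h1 (0.62) and h2 (0.70) and among Xist-high libraries in h2 (0.85, with 1 h2 library), and it missed the threshold in h4 with the Xist covariate (-0.98). Il1r1 in h4 missed it with limma on log2 TPM (0.64). Uncalled values that changed sign in h1 were Il1r1 (-0.11) and Tyr (-0.075) with the Xist covariate and Tyr among Xist-high libraries (-0.16). The odds ratio of calls near Rorb in h1 was 1.52 with no filter and 2.33 with the GC offset, near Rorb in h2 it was 4.10 among Xist-high libraries, and near Rorb in h4 it was 2.53 with limma. Near Il1r1 in h4 it was 1.71 with no filter, 1.61 with only the groups compared, 0.597 with limma, 1.69 with the GC offset, 1.72 among Xist-high libraries and 1.42 in a 40 Mb window. Near Tyr in h2 it was 0.909 with no filter, 0 with limma, 0.904 with the GC offset and 0 among Xist-high libraries.

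Leaving out 1 library at a time gave counts of 22 to 166 for h1, 18 to 348 for h2, 230 to 1111 for h4 and 18 to 505 for the mean against WT, 44 to 160 for h2 against h1, 313 to 896 for h4 against h1 and 251 to 619 for h4 against h2, with 5 to 63 shared calls and 8 to 13 lists for h2. For each count against WT the highest value came without WT replicate 3. Rorb ranged from 0.61 to 0.85 in h2, from -1.02 to -0.93 in h4 and from -0.016 to 0.29 for h2 against h1. Tyr ranged from -0.012 to 0.27 in h1 and from -0.063 to 0.40 for h4 against h1. The odds ratios ranged from 1.33 to 2.57 near Il1r1 in h4, from 1.72 to 6.45 near Rorb in h1, from 1.07 to 3.77 near Rorb in h2, from 0.821 to 1.48 near Rorb in h4 and from 0 to 3.04 near Tyr in h2.

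With the replicate block, 204 genes were called for h2 against h1. Libraries of h1 and h2 with the same number had correlations of their deviations of -0.147, -0.112 and 0.028, so the numbers do not pair the samples. Labels of the other groups share fewer than 2 numbers, so no paired analysis of them was possible. Replicate numbers of WT and h4 follow only sample order.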

Other observations

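Levels of genes that follow the state of the animal are given here as values, since none of those named was called in any of the 7 comparisons. Of the 12 glucocorticoid-responsive genes, Fkbp5, a cochaperone of the glucocorticoid receptor, stood at 36.6 CPM in WT, 48.9 in h1, 24.9 in h2 and 30.1 in h4. Sgk1 stood at 99.2, 176, 72.1 and 124 CPM, Tsc22d3 at 105, 139, 79.9 and 95.1, and Hif3a at 11.3, 16.7, 3.62 and 9.68. Per2, a core clock gene, was at 34.2, 36.2, 21.9 and 31.4 CPM, and Per1 at 72.8, 74.99, 56.0 and 93.6. With an estimated correlation the glucocorticoid list passed in no comparison, the smallest adjusted p being 0.0699, for h2 against h1. The labels give neither the hour of dissection nor the handling of the mice.

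Near Tyr on chromosome 7, a locus at which the h2 background differs, 11 of 253 genes within 20 Mb were called in h4 (4.35% against 4.59% elsewhere, odds ratio 0.944, Fisher's exact p = 1). Among them, and chosen after their values were seen, Mfge8 rose by 0.30 (adjusted p = 0.000932) and Rlbp1 fell by 0.54 on the log2 scale (adjusted p = 0.000585) in h4 against WT.

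The principal components of log CPM over all tested genes did not follow genotype alone. Component 1, with 18.8% of the variance, ran from -14.9 to -5.98 in the 7 female libraries and 10.1 to 24.4 in the 5 male. Component 2, with 12.7%, placed the 3 h4 libraries at -20.4 to -15.2. Haemoglobin gene Hbb-bs varied within groups, at 99.9, 117 and 225 CPM in WT and 73.6 to 179 in the mutants.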
